A study of Brugia malayi
Wolbachia endosymbiont strain TRS of Brugia malayi with 12 samples.

How the data were processed

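The series holds 12 libraries of Brugia malayi larvae taken from gerbils at days 3, 7, 11 and 14 post infection, 3 per day. Per the labels, total RNA of whole worms was extracted with Trizol and RNeasy columns, depleted of ribosomal RNA with Terminator exonuclease, made into libraries with ScriptSeq v2 and sequenced single-end on a Genome Analyzer IIx. The deposited values are raw counts, whole numbers per gene ID, in 1 table for B. malayi and 1 for its Wolbachia, with a column per library. The submitters' processing notes name CASAVA 1.8, cutadapt 1.2.1, Subread 1.5.0, featureCounts 1.5.0 and edgeR without a version. The genome build and annotation are not given in the sources used here, so no positions are given. It is also not given whether the 3 libraries of a day come from separate animals or pools. They may be technical replicates, and p-values measure only the spread between these samples.

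The B. malayi table has 11535 entries for 11434 IDs, since 96 IDs occur on 197 of them, and entries with the same ID were summed. A RefSeq gene table of assembly B_malayi-4.0 served for names only: 8652 IDs matched, 2782 did not, and 3741 of those matched have a symbol styled after Caenorhabditis elegans. Of the 865 Wolbachia IDs, 0 matched a gene name, so the 18 Wolbachia gene lists fixed in advance could not be tested and no Wolbachia gene was identified by name. Total counts per library were 2534416 to 7084642 for B. malayi and 50370 to 970171 for Wolbachia. Counting intervals, at 95%, cover counting error only.

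The Wolbachia share was the ratio of Wolbachia to B. malayi counts in each library, compared on the log2 scale with two-sided exact permutation tests, and over the 4 days with an exact permutation of the day labels. Genes of each organism were tested separately with edgeR 4.0.16 (R 4.3.3), each on its own library totals scaled by trimmed-mean (TMM) factors. The default filter on low counts by day, a model with 1 mean per day over all 12 libraries, and quasi-likelihood F tests were used. CPM values used the same scaled totals. The comparisons were day 7 against 3, day 11 against 7, day 14 against 11, L4 (mean of days 11 and 14) against L3 (mean of days 3 and 7), and any difference over the 4 days. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 with no minimum fold. After filtering, 8964 B. malayi and 658 Wolbachia genes were tested. On simulated data built from these libraries, genes changed 2-fold were called in 71.6% to 88.1% of cases in B. malayi and in 29.9% to 91.0% in Wolbachia, over the 4 comparisons. The lowest Wolbachia value was that of day 7 against day 3. The highest percent of false calls was 6.90 in B. malayi and 7.95 in Wolbachia. Each simulated comparison changed 200 genes, far fewer than were called in the real B. malayi data, and had no replicate-number effect. In Wolbachia, the 200 changed outnumbered the 7 to 177 genes, of 658 tested, that were called in the 4 real comparisons. The percentages hold for that setting and may differ for the real tests.

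Gene lists of B. malayi, 20 in number, were defined by whole-symbol patterns before the data were examined, as were the comparisons, the rule for named genes and the first set of other settings. They were cuticle collagens, cuticle modification and moulting factors, cathepsins and other papain-family peptidases, astacin metalloproteases, peptidase inhibitors, chitin metabolism, nuclear hormone receptors, hedgehog-related and patched-related proteins, larval secreted antigens, cytosolic ribosomal proteins, the mitochondrial respiratory chain and ATP synthase, glycolysis, muscle contractile proteins, DNA replication and cell division, histones, chaperones and heat shock proteins, the proteasome, redox defence, neurotransmitter-gated channels, and germline and sperm markers. The 17 with at least 5 tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted within each comparison, 68 tests in all. Peptidase inhibitors, larval secreted antigens and histones, with 1, 4 and 1 tested members, were described gene by gene.

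Named genes were chosen by rule. In B. malayi they were the 6 largest folds each way per comparison of consecutive days, and 4 each way for L4 against L3. These were taken among called genes with a mean log2 CPM at or above the median, non-overlapping libraries and a usable name. The member of each list with the smallest adjusted p per comparison of consecutive days was added. For Wolbachia, without names, at most 2 IDs each way were taken per comparison. Wbm9001 and Wbm9003 were named after their counts had been seen.

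Other settings chosen at that time were RLE factors, no filter on low counts, DESeq2 1.42.0, the replicate number as a block, only the 2 days compared, each library left out in turn, the B. malayi library sizes for Wolbachia, and for lists an estimated correlation and fry. For the share they were the 10 most abundant IDs left out, effective host library sizes, and the 67 B. malayi tRNA and rRNA IDs left out. Settings added after the data were seen were leaving out the 4 libraries numbered 2, matched IDs only, Wolbachia without its 2 most abundant IDs, libraries thinned to the smallest total, list tests with the block, with the block and an estimated correlation, or without members known by name pattern only. Deviations of the libraries from their day means were compared to see whether replicate numbers pair libraries across days. Such deviations cancel out within a day, so positive same-number correlations make other-number ones negative on average, and the latter are no separate evidence. In B. malayi the 18 same-number pairs correlated at 0.225 to 0.524 across genes and other-number pairs at -0.346 to 0.0272, and all 12 libraries correlated best with their own number, so the numbers pair libraries. With the block, the common biological coefficient of variation went from 11.7% to 4.24%, and 1197 genes had a replicate-number effect. In Wolbachia the same-number correlations were -0.0573 to 0.190, and 2 libraries correlated best with their own number. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used for tables, permutations and plots.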

Results

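Brugia malayi is a filarial nematode of humans, and its cells carry Wolbachia, a bacterium that passes from mother to offspring. Larvae were taken from gerbils at 4 times after infection, days 3, 7, 11 and 14, with 3 libraries per day and 12 in all. Whole-worm RNA was sequenced, and reads of the worm and of the bacterium were counted from the same libraries. Days 3 and 7 carry the label L3, the larval stage that enters the mammalian host, and days 11 and 14 the label L4, the stage that follows the moult. A difference between the stages is therefore also a difference between days. The comparisons of consecutive days ask how both transcriptomes changed before, across and after the change of stage label. Total counts per library ranged from 2534416 to 7084642 for B. malayi and from 50370 to 970171 for Wolbachia. Among the Wolbachia counts, 2 IDs, Wbm9001 and Wbm9003, held 66.9% and 24.2%, and they were singled out after their counts had been seen. Outside them, a library held 4934 to 5961 counts at day 3, 20059 to 53922 at day 7, 52120 to 73116 at day 11 and 57985 to 82164 at day 14.

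Wolbachia reads rose against worm reads on each day sampled. For every 100 B. malayi counts there were 0.986 ± 0.0196 Wolbachia counts at day 3 (SD, n = 3), 6.31 ± 0.249 at day 7, 21.1 ± 1.00 at day 11 and 28.9 ± 1.70 at day 14. The ratio was 6.40-fold higher at day 7 than at day 3 (log2 2.68, SE 0.04), 3.35-fold higher at day 11 than at day 7 (log2 1.74, SE 0.05) and 1.37-fold higher at day 14 than at day 11 (log2 0.45, SE 0.06). In each step, all 3 libraries of the later day lay above all 3 of the earlier day, and the two-sided exact permutation p was 0.1, the smallest that 3 libraries against 3 can give. From day 3 to day 14 the ratio rose 29.3-fold (log2 4.87). An exact permutation test over the 4 days gave p = 6.49e-05, the smallest that the 369600 assignments can give. The 6 L4 libraries had a mean log2 ratio of -2.02 ± 0.26 and the 6 L3 libraries -5.33 ± 1.47, a 9.90-fold difference (two-sided exact permutation p = 0.00216, the smallest that 924 assignments can give). That p takes the libraries as units. The libraries of a stage come from only 2 days, within which the SD was 0.03 to 0.08, so it is no measure of the stage apart from the days. The rise was not limited to the most abundant IDs. Wbm9001 went from 0.659 ± 0.0187 to 19.8 ± 1.45 per 100 B. malayi counts between days 3 and 14 (30.1-fold), Wbm9003 from 0.232 ± 0.00274 to 6.67 ± 0.183 (28.8-fold), and the other 863 IDs together from 0.0961 ± 0.00180 to 2.38 ± 0.184 (24.8-fold).

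**Figure D1:**
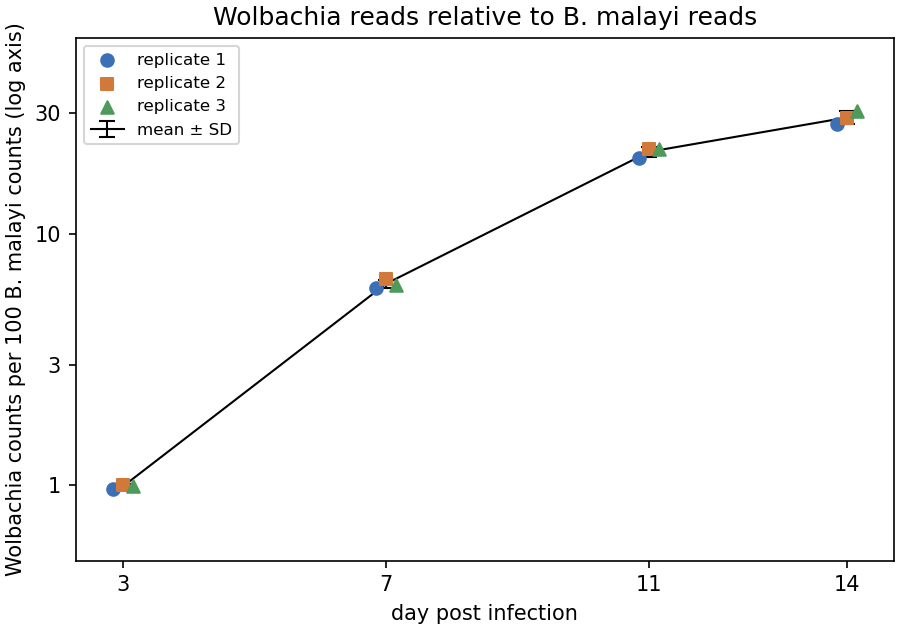
Wolbachia counts per 100 B. malayi counts (log axis) against day post infection, with a marker for each of the 12 libraries, offset sideways by replicate number, and the mean ± SD of each day. The day means rise from 0.986 at day 3 to 28.9 at day 14, and the 3 libraries of a day lie close together.

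In B. malayi, 6922 of 8964 tested genes differed between at least 2 of the 4 days in edgeR's quasi-likelihood test. Between days 3 and 7, 2534 genes rose and 2428 fell. From day 7 to day 11, 2338 rose and 2377 fell, and from day 11 to day 14, 1245 rose and 1324 fell. Changes of at least 2-fold were made by 885 of the rising and 370 of the falling genes between days 3 and 7, by 380 and 675 between days 7 and 11, and by 87 and 113 between days 11 and 14. The libraries of the 2 days did not overlap for 5499, 5260 and 3775 genes in the 3 steps, where chance separates 10% of genes with 3 libraries against 3. IDs that could not be matched to the gene table took 19.0% ± 2.06 of the B. malayi counts at day 3 (SD, n = 3), 20.4% ± 1.51 at day 7, 27.6% ± 2.00 at day 11 and 30.9% ± 3.86 at day 14. They entered the tests but carry no name. For the genes chosen by rule, the libraries did not overlap in the comparisons for which they were chosen. The rule itself required this, except of the members added from lists, so it is no further evidence for those genes.

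**Figure D2:**
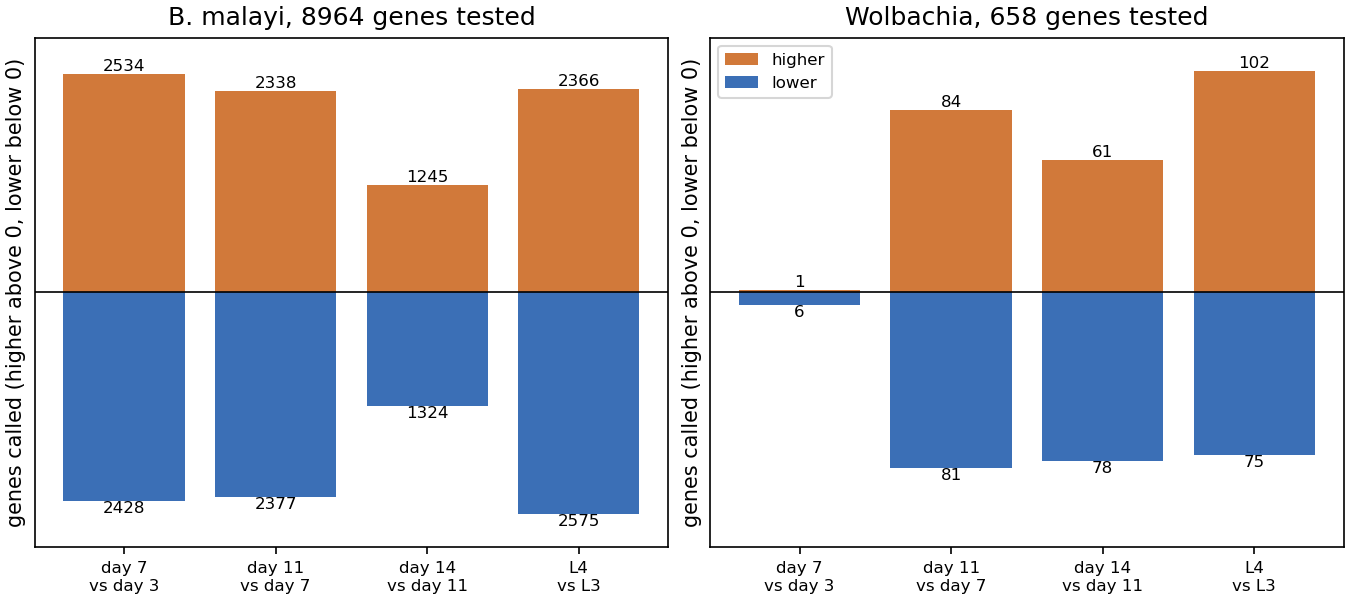
Numbers of genes called higher (above 0) and lower (below 0) in each comparison, for B. malayi (8964 genes tested) and Wolbachia (658 genes tested), each panel on its own scale. B. malayi calls run from 1245 higher at day 14 against day 11 to 2575 lower in L4 against L3, and Wolbachia calls from 1 to 102.

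Between days 3 and 7 hedgehog-related and patched-related genes rose as a group, while cuticle collagen and cuticle modification genes went both ways. Among genes with a C. elegans-style symbol, a mean level at or above the median and non-overlapping libraries, the largest rises were those of the ground-like, hedgehog-related genes Bma-grl-7 (Bm1_34770) and Bma-grl-4 (Bm1_52595), the tyrosinase gene Bma-tyr-2.2 (Bm1_04885), the cuticle collagens Bma-col-104 (Bm1_11115) and Bma-col-14 (Bm1_00815), and Bma-abu-12.1 (Bm1_04860). Bma-grl-4 went from 13.9 ± 1.47 to 2326 ± 578 CPM (counts scaled to the library's total; SD, n = 3), a 168-fold rise. Bma-tyr-2.2 rose 432-fold, Bma-col-104 143-fold, Bma-col-14 105-fold and Bma-abu-12.1 78.9-fold, with adjusted p values from 5.50e-15 to 1.92e-11. Bma-grl-7 had 2 counts over the 3 day 3 libraries and 7708 over those of day 7, a ratio of 4610 with a counting interval of 1276 to 38072 at 95%. The 6 named genes with the largest falls had mean levels of 150.3 to 1048 CPM at day 3. Bma-sym-1 (Bm1_40135), which encodes a secreted leucine-rich repeat protein, went from 724 ± 17.3 to 17.4 ± 0.650 CPM, a 41.4-fold fall. Bma-fbn-1 (Bm1_45425), a fibrillin-like matrix protein, fell by 4.91 on the log2 scale, Bma-fkb-7 (Bm1_35815), a peptidyl-prolyl isomerase, fell 29.7-fold, and Bma-hum-4.2 (Bm1_00070), an unconventional myosin, 22.1-fold. The collagen gene Bma-dpy-7.2 (Bm1_06810) fell 22.5-fold and the cuticlin-like gene Bma-cutl-25 (Bm1_16475) 15.2-fold, and the adjusted p values of these 6 genes lay between 8.97e-15 and 3.67e-12.

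Hedgehog-related and patched-related proteins, a family expanded in nematodes, rose as a group between days 3 and 7. Of 25 tested members 18 rose, 5 fell and 2 had no call, with the same counts adjusted over the list alone (camera adjusted p = 1.63e-05, and 0.0119 with an estimated correlation). Bma-ptr-23 (Bm1_05960) rose from 18.6 ± 0.786 to 467 ± 7.75 CPM (log2 4.65, SE 0.06, adjusted p = 3.22e-15). DNA replication and cell division genes rose, 21 of 43 against 3 that fell and 19 with no call, and 22 against 3 adjusted over the list alone (camera adjusted p = 0.00551, and 0.0284 with an estimated correlation). Bma-mcm-7 (Bm1_31460), a subunit of the replicative helicase, rose 7.44-fold. Genes of the mitochondrial respiratory chain and ATP synthase fell, 17 of 25 against 1 that rose and 7 with no call, the same adjusted over the list alone (camera adjusted p = 0.000104, and 0.0119 with an estimated correlation). Bma-atp-5 (Bm1_16555) fell 1.70-fold. Proteasome genes fell, 15 of 33 against 2 that rose and 16 with no call, again the same adjusted over the list alone (camera adjusted p = 0.00756, and 0.0337 with an estimated correlation). That call was lost with an estimated correlation and the replicate number as a block (adjusted p = 0.0888). Bma-pas-5 (Bm1_37390), a core subunit, fell 1.98-fold. Of 74 cytosolic ribosomal protein genes 56 fell, 1 rose and 17 had no call, and 59 fell adjusted over the list alone (camera adjusted p = 4.96e-11, median log2 change -0.41). That call was lost with an estimated correlation (adjusted p = 0.0802), and held with an estimated correlation and the replicate number as a block (0.0107). Bma-rack-1 (Bm1_36465), a ribosome-bound scaffold, fell 1.73-fold. Muscle contractile genes rose in 10 of 15 members and fell in 2, with 3 not called, the same adjusted over the list alone (camera adjusted p = 0.0360, but adjusted p = 0.269 with an estimated correlation, and 0.0514 without day 7 replicate 2). Bma-unc-87 (Bm1_49075), a calponin-related thin-filament protein, rose 2.10-fold. Neurotransmitter-gated channel genes rose in 11 of 27 members and fell in 1, with 15 not called, and in 10 against 1 adjusted over the list alone (camera adjusted p = 0.0296, but adjusted p = 0.0802 with an estimated correlation). Bma-lgc-34 (Bm1_02760) rose 2.77-fold.

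The lists of cuticle genes held members that went strongly both ways between days 3 and 7. Of 19 cuticle collagens 9 rose and 7 fell, and the list had no call (camera adjusted p = 0.60). Bma-dpy-8.2 (Bm1_32145) fell 28.1-fold, from 108 ± 2.04 to 4.26 ± 1.73 CPM. Of 40 cuticle modification and moulting factors 17 rose and 14 fell (camera adjusted p = 0.925, upward, while fry's direction was downward). Bma-lpr-5 (Bm1_38110), a lipocalin-related matrix protein, fell 4.23-fold. Astacin metalloproteases, some of which process cuticle collagens in Caenorhabditis elegans, rose in 7 of 11 and fell in 1. The test gave an adjusted p of 0.0564, and between 0.0430 and 0.04998 when day 3 replicate 3, day 11 replicate 1, day 14 replicate 1 or day 14 replicate 3 was left out. Bma-nas-30 (Bm1_49145) rose 15.7-fold. Of the 5 chitin genes 4 fell, while the chitin synthase gene Bma-chs-2 (Bm1_17930) rose 15.9-fold from 0.411 ± 0.363 CPM (list adjusted p = 0.60). Among 21 nuclear hormone receptors 6 rose and 5 fell (camera adjusted p = 0.925, downward, with a median of log2 0.13 and a mean of -0.01). Bma-nhr-23 (Bm1_49990), whose C. elegans counterpart is required for moulting, fell from 92.9 ± 4.42 to 5.29 ± 1.12 CPM (log2 -4.05, SE 0.12). All 4 tested larval secreted antigens fell, among them Bma-alt-2 (Bm1_26880), named after an abundant larval transcript, which fell by 3.00 on the log2 scale (SE 0.25). Redox defence genes went both ways, 3 up and 4 down of 9 (camera adjusted p = 0.882, downward, fry upward, with a median of log2 -0.22 and a mean of 0.45). The mean was carried upward by Bma-gsto-3 (Bm1_44425), an omega-class glutathione transferase, which rose 45.4-fold. Chaperones had 13 up and 15 down of 41 (camera adjusted p = 0.60, downward, with a mean of log2 0.02), and Bma-enpl-1 (Bm1_39715) fell from 2552 ± 128 to 1265 ± 20.1 CPM. Glycolysis had 6 up and 3 down of 14 (adjusted p = 0.673), with Bma-hxk-2 (Bm1_14445), a hexokinase, up 2.42-fold. Germline and sperm markers had 3 up and 1 down of 8 (adjusted p = 0.60), and Bma-him-6 (Bm1_49360) rose 1.27-fold. Of 5 papain-family list members 1 rose and 2 fell, with a median of log2 0.07, a mean of -0.16 and a downward test (adjusted p = 0.701). The 5 include members known by name pattern only, such as Bma-cpf-1. Without them the list fell below the minimum of 5 and could not be tested in any comparison. The cathepsin L gene Bma-cpl-1.1 (Bm1_18805) fell 1.86-fold. Adjusted over the list alone, the counts of the lists in this paragraph were the same.

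From day 7 to day 11, the step in which the label changes from L3 to L4, hedgehog-related and patched-related genes fell as a group and a cathepsin L gene rose. Bma-cpl-1.1, whose C. elegans counterpart is needed for embryonic development, rose 8.36-fold from 38.3 ± 1.91 to 319 ± 15.5 CPM (log2 3.06, SE 0.11, adjusted p = 8.07e-11). Bma-mpst-7 (Bm1_51915), a sulfurtransferase, rose 4.58-fold, the histone gene Bma-his-73 (Bm1_02495) 3.64-fold, Bma-lfi-1.1 (Bm1_12640) 3.26-fold and Bma-hum-4.2 3.24-fold. Bma-ketn-1 (Bm1_54260), which encodes the thin-filament protein kettin, rose 3.16-fold from 338 ± 15.4 to 1068 ± 44.6 CPM. The adjusted p values of these 5 genes ran from 1.29e-10 to 6.40e-06. The 6 named genes with the largest falls had mean levels of 0.0944 to 3.08 CPM at day 3 and of 141 to 475 CPM at day 7. Bma-grl-7 fell from 475 ± 25.4 to 2.30 ± 0.522 CPM and Bma-col-104 from 151 ± 20.9 to 0.895 ± 0.595 CPM, which were falls of 205-fold and 168-fold. Bma-col-14 fell 47.1-fold, Bma-tyr-2.2 35.9-fold, Bma-gsto-3 23.8-fold and Bma-hpo-36 (Bm1_25290) by log2 -5.13, with adjusted p values of at most 2.99e-10.

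Cuticle collagens fell together between days 7 and 11. None of the 19 rose, 14 fell and 5 had no call, and 15 fell adjusted over the list alone (camera adjusted p = 3.51e-07, but adjusted p = 0.0533 with an estimated correlation). With an estimated correlation and the replicate number as a block the call held (0.0152). Bma-col-164 (Bm1_26195) fell by 3.58 on the log2 scale. Cuticle modification and moulting factors fell in 25 of 40 members and rose in 3, with 12 not called, the same adjusted over the list alone (camera adjusted p = 0.000135, but adjusted p = 0.0533 with an estimated correlation). The cuticlin gene Bma-cut-5 (Bm1_38185) fell 4.22-fold. Astacins fell in 7 of 11 and rose in 2, with 2 not called, and 8 fell adjusted over the list alone (camera adjusted p = 0.0136, but adjusted p = 0.0774 with an estimated correlation). Bma-nas-30 fell 22.9-fold, from 79.8 ± 2.59 to 3.50 ± 1.68 CPM. Hedgehog-related and patched-related genes fell in 20 of 25 and rose in 1, with 4 not called, and 2 rose adjusted over the list alone (camera adjusted p = 1.23e-07, and 0.00430 with an estimated correlation). Bma-ptr-23 fell 6.07-fold. Muscle contractile genes rose in 10 of 15 and fell in 3, with 2 not called, the same adjusted over the list alone (camera adjusted p = 0.00578, but adjusted p = 0.188 with an estimated correlation). Bma-unc-22 (Bm1_39425), the giant muscle protein twitchin, rose from 2018 ± 71.7 to 5498 ± 164 CPM. Cytosolic ribosomal protein genes rose in 30 of 74 and fell in 6, with 38 not called, and in 29 against 6 adjusted over the list alone (camera adjusted p = 0.00687, but adjusted p = 0.420 with an estimated correlation). Bma-rla-0 (Bm1_31485), a ribosomal stalk protein, rose from 1985 ± 72.9 to 3063 ± 57.0 CPM.

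The remaining lists had no call between days 7 and 11. Mitochondrial respiratory chain genes had 10 up and 3 down of 25, DNA replication and cell division 15 up and 5 down of 43, neurotransmitter-gated channels 2 up and 12 down of 27 and germline markers 4 up and 1 down of 8, all at an adjusted p of 0.249. Bma-gld-2 (Bm1_48860), a cytoplasmic poly(A) polymerase of the germline in C. elegans, rose 1.87-fold, and Bma-lgc-44 (Bm1_42380) fell 1.51-fold. Bma-cox-6A (Bm1_25100), a cytochrome c oxidase subunit, fell 1.40-fold. Bma-cdk-12 (Bm1_46210), which rose 1.41-fold, entered the replication list by the pattern of its name and is known as a kinase of transcription. Redox defence had 5 up and 1 down of 9 (adjusted p = 0.249, upward, with a median of log2 0.28 and a mean of -0.25). The mitochondrial thioredoxin gene Bma-trx-2 (Bm1_27930) rose 1.55-fold. Chitin genes had 2 up and 0 down of 5 (adjusted p = 0.423), and Bma-chs-1 (Bm1_35215) rose 2.77-fold. Nuclear hormone receptors had 3 up and 5 down of 21 (adjusted p = 0.537), with Bma-nhr-85 (Bm1_55880) up 2.18-fold. Chaperones had 13 up and 14 down of 41 (adjusted p = 0.744, upward, with a mean of log2 -0.05), proteasome genes 12 up and 9 down of 33 and glycolysis 5 up and 4 down of 14, both at an adjusted p of 0.520. Bma-hsp-110 (Bm1_23190) rose 1.55-fold, Bma-rpn-2 (Bm1_32775) rose 1.42-fold and Bma-hxk-2 fell 1.72-fold. The papain-family list had 2 up and 2 down of 5 (adjusted p = 0.520). Its member with the smallest adjusted p, Bma-cpf-1 (Bm1_43290), fell 1.48-fold and is known as an RNA cleavage factor that shares only the name pattern of the list. Of 4 larval antigens 2 rose, and Bma-mif-1 (Bm1_28435), a macrophage migration inhibitory factor homologue, rose 1.32-fold (adjusted p = 0.0198). That call was lost without day 7 replicate 2 (adjusted p = 0.0819), day 11 replicate 1 (0.0649) or day 11 replicate 3 (0.0796), and held with the replicate number as a block (1.47e-08). Adjusted over the list alone, chaperones had 14 up, proteasome genes 11 down and germline markers 2 down, and the other lists of this paragraph kept their counts.

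Between days 11 and 14, both within the L4 label, fold changes were smaller and no gene list rose. The acyl-CoA-binding protein gene Bma-acbp-3 (Bm1_21135) rose 2.52-fold, the RNA polymerase II subunit gene Bma-rpb-4 (Bm1_25045) 2.44-fold, and Bma-snb-1 (Bm1_53075), the synaptic vesicle protein synaptobrevin, 2.35-fold from 134 ± 7.79 to 316 ± 16.2 CPM. Bma-pfd-2 (Bm1_14985), a prefoldin subunit, rose 2.22-fold, Bma-dro-1 (Bm1_32980) 2.21-fold and Bma-ufbp-1 (Bm1_54325) 2.10-fold, and the adjusted p values of these 6 genes ran from 1.71e-07 to 3.01e-05. Bma-grl-7 had 24 counts at day 11 and 2 at day 14, a ratio of 9.34 with a counting interval of 2.32 to 81.5 at 95%. The patched-related gene Bma-ptr-20 (Bm1_43125) fell from 6.16 ± 1.46 to 2.17 ± 0.804 CPM (adjusted p = 0.00632), Bma-hpo-36 fell 2.68-fold (0.0105) and Bma-gsto-3 2.33-fold (0.0126). Over the 3 day 14 libraries these 3 genes had 17, 12 and 21 counts. The call of Bma-ptr-20 was lost without the 4 libraries numbered 2 (adjusted p = 0.0687), that of Bma-hpo-36 without day 14 replicate 3 (0.107), and that of Bma-gsto-3 without day 14 replicate 2 (0.0505) or the libraries numbered 2 (0.0964). Bma-strl-1.3 (Bm1_19490) fell 1.95-fold (adjusted p = 0.00125) and the cadherin gene Bma-cdh-10 (Bm1_27425) 1.81-fold (adjusted p = 0.000185).

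The list calls between days 11 and 14 were 2 falls. Hedgehog-related and patched-related genes fell in 12 of 25 and rose in 1, with 12 not called, and 13 fell adjusted over the list alone (camera adjusted p = 0.00543, but adjusted p = 0.0540 with an estimated correlation). Bma-ptr-23 fell 1.45-fold. Neurotransmitter-gated channels fell in 6 of 27 and rose in none, with 21 not called, the same adjusted over the list alone (camera adjusted p = 0.00543, but adjusted p = 0.0540 with an estimated correlation). The estimates for these 2 lists, 0.00306 and 0.00361, were below the preset 0.01, so a higher correlation did not end their calls. Bma-unc-29 (Bm1_35890), an acetylcholine receptor subunit of muscle, fell 1.36-fold. Chaperones had 13 up and 3 down of 41 (camera adjusted p = 0.107), and Bma-dnj-24 (Bm1_45900) rose 1.66-fold. Among the other lists, cuticle modification factors had 6 up and 2 down of 40 and nuclear hormone receptors 3 up and 0 down of 21, both at an adjusted p of 0.340, and redox defence had 0 up and 3 down of 9 (adjusted p = 0.403). Bma-nhr-23 rose 4.05-fold, from 0.889 ± 0.406 to 3.61 ± 0.614 CPM, a level far under that of day 3. The tetraspanin gene Bma-tsp-15 (Bm1_40005) fell 1.41-fold and the thioredoxin reductase gene Bma-trxr-1 (Bm1_36410) 1.26-fold. Cytosolic ribosomal proteins had 9 up and 14 down of 74, DNA replication 5 up and 4 down of 43 and the papain-family list 1 up and 1 down of 5, each at an adjusted p of 0.640. Bma-rpl-38 (Bm1_30500) fell 1.37-fold, Bma-cdk-12 1.29-fold and the cathepsin Z gene Bma-cpz-1 (Bm1_56735) 1.24-fold. Cuticle collagens had 1 up and 0 down of 19, astacins 0 up and 1 down of 11, muscle contractile genes 3 up and 5 down of 15 and proteasome genes 10 up and 8 down of 33, each at an adjusted p of 0.686, and the proteasome test pointed up with a median of log2 -0.00. Bma-tnc-2 (Bm1_43315), a troponin C, fell 1.67-fold, Bma-nas-15 (Bm1_38890) fell 1.55-fold and Bma-pas-6 (Bm1_17805) rose 1.81-fold. The collagen gene Bma-dpy-2 (Bm1_47145) rose 1.86-fold (adjusted p = 0.0278). Its call was lost without day 11 replicate 1 (adjusted p = 0.0578), day 11 replicate 2 (0.0891), day 14 replicate 1 (0.120) or the libraries numbered 2 (0.155). Germline markers had 2 up and 2 down of 8 (adjusted p = 0.703), chitin genes 0 up and 0 down of 5 and glycolysis 4 up and 2 down of 14 (both 0.849, the latter upward with a median of log2 -0.09). Mitochondrial genes had 3 up and 2 down of 25 (adjusted p = 0.861, upward, with a mean of log2 -0.01 and fry downward). Bma-him-1 (Bm1_12960) fell 1.30-fold, Bma-hxk-3 (Bm1_31750) rose 1.32-fold and Bma-nduf-7 (Bm1_48645) rose 1.22-fold. Of 4 larval antigens 1 fell, the fatty-acid and retinol-binding protein gene Bma-far-1 (Bm1_41425), by 0.34 on the log2 scale. A block on the replicate number also called Bma-mif-1 lower (log2 -0.11, adjusted p = 0.0296). The only tested member of the peptidase inhibitor list, Bma-tim-1 (Bm1_21675), fell 1.33-fold, and its C. elegans namesake is a Timeless homologue rather than an inhibitor. At the earlier steps it had log2 changes of -0.01 and 0.10 and no call. Adjusted over the list alone, collagens had 0 up, cuticle factors 5 up, papain-family members 2 up, glycolysis 3 down, muscle genes 4 up, replication 4 up, chaperones 14 up and proteasome genes 11 up and 9 down, and the other lists kept their counts.

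**Figure D3:**
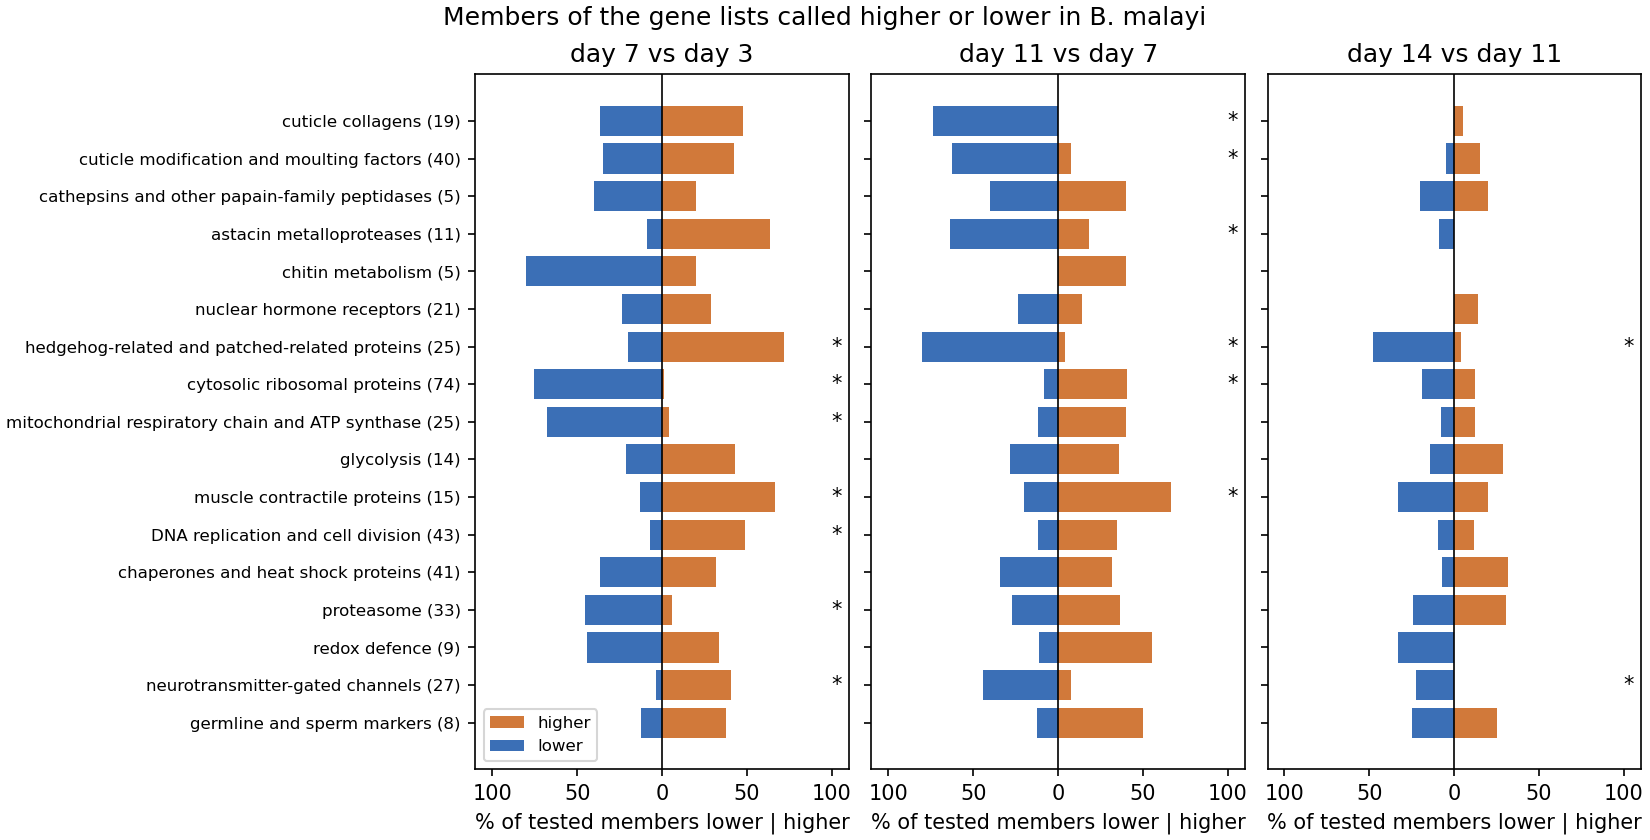
Percent of the tested members of each gene list called lower (left) and higher (right) in the 3 comparisons of consecutive days, with the number of tested members in parentheses and an asterisk where camera called the list with its preset correlation. Hedgehog-related and patched-related proteins, 25 tested, lie mostly to the right at day 7 against day 3 and mostly to the left in the later steps.

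Pooling the days by stage, 2366 B. malayi genes were higher in L4 (days 11 and 14) and 2575 lower than in L3 (days 3 and 7), 427 and 484 of them by at least 2-fold. The 6 libraries of L4 did not overlap the 6 of L3 for 1435 genes, so most of the called genes did not separate the stages library by library. Chance would give 0.216% if all 12 libraries were interchangeable. They are grouped by day, and genes that differ between days can separate the stages more often, so that rate cannot serve to judge the stage label. The cathepsin L gene Bma-cpl-1.1 stood higher in L4, and collagens lower. Bma-lntl-1.1 (Bm1_05910) was 9.62-fold higher, with 2.26 ± 1.07, 32.7 ± 3.74, 66.8 ± 6.46 and 103.7 ± 8.61 CPM on the 4 days. Bma-cpl-1.1 was 6.21-fold, Bma-lfi-1.1 4.78-fold and Bma-his-73 3.94-fold higher. Bma-dpy-7.2 was lower, with 150.3 CPM at day 3, 6.76 at day 7 and only 4 counts over the 3 libraries at day 11 and 2 at day 14. Bma-ptr-20 was 19.4-fold lower, Bma-cutl-25 16.7-fold and the lipocalin-related gene Bma-lpr-3 (Bm1_38120) 12.3-fold, from 690.1 ± 41.4 CPM at day 3 and 57.6 ± 6.92 at day 7 to 18.2 ± 3.01 at day 14. The adjusted p values of these 8 genes lay between 3.00e-12 and 1.37e-07.

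Muscle contractile genes were higher in L4 in 12 of 15 members and lower in 2, the same adjusted over the list alone (camera adjusted p = 2.37e-05, and 0.0464 with an estimated correlation). That call was lost with an estimated correlation and the replicate number as a block, as was that of astacins (adjusted p = 0.0620 for both). DNA replication and cell division genes were higher in 22 of 43 and lower in 4, also the same adjusted over the list alone (camera adjusted p = 0.000127, and 0.0185 with an estimated correlation). This difference lay mainly in the low level at day 3, with a median log2 change of 0.36 from day 3 to day 7. From day 7 to day 11 the median was 0.06, and the list had no call (camera adjusted p = 0.249). Collagens were lower in 15 of 19 and higher in 0, or 1 adjusted over the list alone (camera adjusted p = 1.17e-05, and 0.0464 with an estimated correlation). Cuticle modification factors were lower in 25 of 40 and higher in 5 (camera adjusted p = 1.17e-05, and 0.0220 with an estimated correlation), astacins lower in 8 of 11 and higher in 1 (0.00792, and 0.0464 with an estimated correlation) and hedgehog-related and patched-related genes lower in 17 of 25 and higher in 4 (0.000191, and 0.0213 with an estimated correlation). Adjusted over the list alone, these 3 lists kept their counts. The lower level of the hedgehog-related and patched-related list rested on its high level at day 7, since 14 of the 25 had mean levels above that of day 3 at both days 11 and 14, and 9 below it at both. Bma-grl-4, for example, stood at 220.4 and 148.6 CPM on those days, above its level at day 3. Cytosolic ribosomal proteins were lower in 29 of 74 and higher in 6, or 28 and 6 adjusted over the list alone (camera adjusted p = 0.0347, but adjusted p = 0.501 with an estimated correlation). Their lower level rested on the high level at day 3. At both days 11 and 14, 62 of the 74 had mean levels below that of day 3 and 2 above it. From day 7 to day 11 their median log2 change was 0.15. Germline and sperm markers were higher in 6 of 8 and lower in 1, the same adjusted over the list alone (camera adjusted p = 0.0347, but adjusted p = 0.109 with an estimated correlation). The germline call was also lost with the replicate number as a block (adjusted p = 0.0501) and without day 3 replicate 2 (0.0506). The ribosomal call was lost without day 3 replicate 2 (0.0519), day 7 replicate 1 (0.0518), day 7 replicate 2 (0.0641), day 11 replicate 3 (0.0664) or day 14 replicate 3 (0.0892). Over all 4 comparisons 23 of the 68 list tests were called, and 6 of 50 random groupings that kept 1 library of each replicate number per day gave at least as many. The lists with no call in L4 against L3 were the mitochondrial respiratory chain (1 higher and 11 lower of 25, adjusted p = 0.129), glycolysis (6 and 1 of 14, 0.123), channels (5 and 12 of 27, 0.250), the proteasome (5 and 12 of 33, 0.250), chaperones (14 and 10 of 41, 0.489), chitin (2 and 0 of 5, 0.489) and nuclear hormone receptors (5 and 7 of 21, 0.647). Redox defence had 4 higher and 3 lower of 9 (0.619, upward, with a median of log2 0.24 and a mean of -0.13), and the papain-family list 2 higher and 3 lower of 5 (0.619, upward, with a median of log2 -0.20 and a mean of 0.52). Of 4 larval antigens 2 were lower, and Bma-tim-1 had no call. A block on the replicate number also called Bma-far-1 lower (log2 -0.09, adjusted p = 0.00883), Bma-mif-1 higher (log2 0.09, 0.00537) and Bma-tim-1 lower (log2 -0.12, 0.0391). Bma-his-73, the single tested member of the histone list, was higher in L4, with no call at the first and last steps (log2 0.54 and -0.30, adjusted p = 0.0519 and 0.279). With the replicate number as a block it was called at both (1.69e-05 and 0.000593). Adjusted over the list alone, channels had 6 higher, Bma-tim-1 was lower and Bma-his-73 was higher also at day 7 against day 3, both with overlapping libraries, and the other lists with no call kept their counts.

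**Figure D4:**
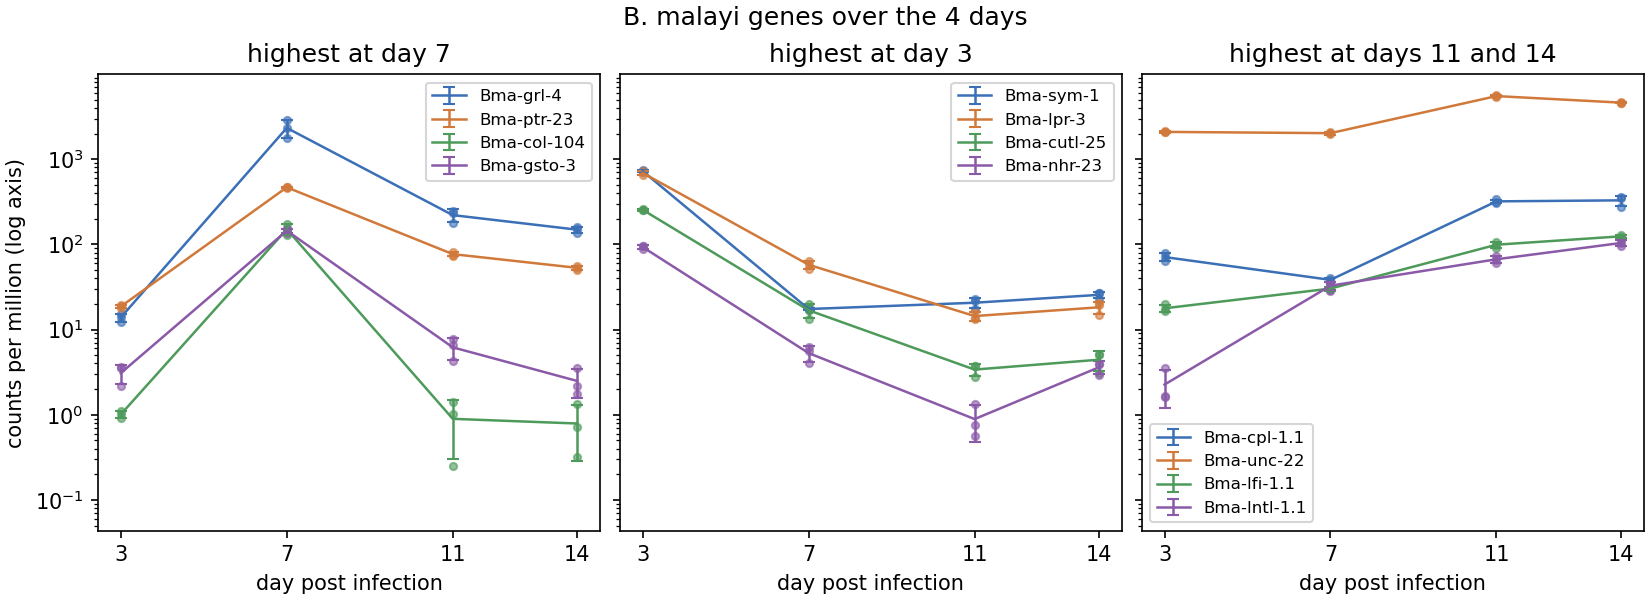
CPM, counts scaled to the library's total (log axis), of 12 B. malayi genes against day post infection, with the 3 libraries of each day as points and the mean ± SD as lines and bars. Genes that rose and then fell around day 7, such as Bma-ptr-23 with 467 CPM at day 7, are on the left, genes that were highest at day 3 in the middle, and genes highest at days 11 and 14 on the right.

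Among the Wolbachia genes, measured on the bacterium's own totals scaled by trimmed-mean factors, 308 of 658 tested differed between at least 2 of the 4 days in edgeR's quasi-likelihood test. The factors were 1.21 to 1.35 at day 7 and at most 0.960 on the other days, so values differ from shares of the bacterium's raw total. Few genes were called between days 3 and 7, with 1 higher and 6 lower, while 120 had an unadjusted p under 0.05. The number higher was 0 without day 3 replicate 3 (60 at an unadjusted p under 0.05), 2 without day 3 replicate 2, day 7 replicate 1 or day 7 replicate 2, 4 without day 14 replicate 1 and 3 without day 14 replicate 2. From day 7 to day 11, 84 rose and 81 fell, 18 and 5 of them by at least 2-fold. From day 11 to day 14, 61 rose and 78 fell with trimmed-mean factors, 79 and 64 with median-ratio (RLE) factors, and 55 and 39 with DESeq2. In L4 against L3, 102 were higher and 75 lower. The libraries did not overlap for 173, 246 and 252 genes in the 3 steps of consecutive days, where chance gives 10%, and for 66 in L4 against L3. There chance would give 0.216% if all 12 libraries were interchangeable, which libraries grouped by day are not. With the worm's library sizes as the scale, the median log2 change of all Wolbachia genes moved from 0.14 to 3.33 between days 3 and 7, from -0.01 to 1.32 between days 7 and 11, from 0.01 to 0.55 between days 11 and 14 and from 0.09 to 3.26 in L4 against L3. On that scale edgeR called 657 higher and 0 lower, 623 and 0, 406 and 5, and 658 and 0, and where it called 0 lower, 0 had an unadjusted p under 0.05. The values of single genes are therefore changes relative to the rest of the bacterium's transcripts. No gene names were used for Wolbachia, so IDs are given as deposited.

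Wbm0239 rose 1.91-fold between days 3 and 7 (log2 0.93, SE 0.23, adjusted p = 0.0149), a call lost without day 3 replicate 2 (adjusted p = 0.102) or day 3 replicate 3 (0.201). Wbm0495 fell from 560.3 ± 21.4 to 295 ± 9.07 CPM (log2 -0.92, SE 0.18, adjusted p = 0.000302) and Wbm0138 from 251 ± 105 to 86.1 ± 28.0 CPM (adjusted p = 0.000765), while with the worm's library sizes both rose, by log2 2.34 and 1.81. The Wbm0138 call was lost without day 3 replicate 1 (adjusted p = 0.225). Over the 3 day 3 libraries, Wbm0239, Wbm0495 and Wbm0138 had only 34, 91 and 41 counts. From day 7 to day 11, Wbm0767 rose 8.99-fold (adjusted p = 1.48e-22) and Wbm0089 5.64-fold (adjusted p = 1.08e-19). Wbm0454 fell 1.98-fold (log2 -0.99) and Wbm7018 by log2 -0.85, and with the worm's library sizes they rose by log2 0.34 and 0.48. From day 11 to day 14, Wbm0193 rose 3.00-fold and Wbm0089 2.47-fold, to 601 ± 19.0 CPM, and Wbm0616 and Wbm0459 fell 2.02-fold and 1.98-fold (adjusted p at most 1.65e-07 for the 4). In L4 against L3, Wbm0767 and Wbm0006 rose. Wbm0767 had 1 count at day 3 and means of 30.2 ± 12.3, 291 ± 29.9 and 595 ± 51.1 CPM at days 7, 11 and 14, and Wbm0006 had 0 counts at day 3 and 19.5 ± 10.3, 89.8 ± 7.40 and 158 ± 19.6 CPM later, so no fold is given for either (adjusted p = 2.39e-27 and 3.90e-13). wBmNew0014 fell 2.25-fold and Wbm0454 2.34-fold, and with the worm's library sizes both were higher, by log2 2.06 and 2.00. Leaving out day 3 replicate 3 lowered the L4 falls from 75 to 49. The falls at day 11 went from 81 to 42 without day 7 replicate 3 and to 52 without day 11 replicate 1, and those at day 14 from 78 to 46 without day 11 replicate 1 or replicate 3.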

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

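The alternatives chosen after the data were seen were leaving out the libraries numbered 2, matched IDs only, Wolbachia without its 2 most abundant IDs, thinned libraries, and list tests with a replicate block or without members known by name pattern only. Of the planned ones, leaving Wolbachia rRNA and tRNA IDs out of the share was not run, since no Wolbachia ID could be identified. Only the 67 B. malayi tRNA and rRNA IDs were left out.

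The rise of the Wolbachia share kept its direction and its call under every alternative run. The log2 rise from day 3 to day 14 lay between 4.83 and 4.91 with 1 library left out and between 4.63 and 5.17 under the others, and L4 against L3 between 3.03 and 3.59 and between 2.89 and 3.50. B. malayi counts stayed within 1.5 times their values under every alternative run. Genes higher at day 7 against day 3, 2534, went from 2289 to 2568 with 1 library left out and from 2152 to 2931 otherwise. Over the 4 days, 6922 went from 6578 to 6862 and from 5929 to 7551.

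Wolbachia counts moved with the worm's library sizes, a scale that carries the rise of the share by construction: 657 higher and 0 lower at day 7 against day 3, 623 and 0 at day 11 against day 7, 406 and 5 at day 14 against day 11, 658 and 0 in L4 against L3, and 658 over the 4 days (edgeR; where 0 were lower, 0 had an unadjusted p under 0.05). Thinning to the smallest total left 159 genes to test. It gave 0 higher at day 7 against day 3 (edgeR; 12 at an unadjusted p under 0.05), 12 higher and 3 lower at day 11 against day 7, 2 and 1 at day 14 against day 11, 23 and 20 in L4 against L3, and 36 over the 4 days. Without the filter 7 were higher at day 7 against day 3, and DESeq2 called 12 lower there and 39 lower at day 14 against day 11; the cause was not tested. With 1 library left out, Wolbachia genes higher at day 7 against day 3 numbered 0 (edgeR; without day 3 replicate 3, 60 at an unadjusted p under 0.05) to 4 (without day 14 replicate 1), 2 without day 3 replicate 2, day 7 replicate 1 or day 7 replicate 2, and 3 without day 14 replicate 2. Genes lower at day 11 against day 7 numbered 42 (without day 7 replicate 3) to 83, with 52 without day 11 replicate 1. Those lower at day 14 against day 11 numbered 46 (without day 11 replicate 1 or 3) to 77, and those lower in L4 49 (without day 3 replicate 3) to 76.

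Of 68 list tests 23 passed with the preset correlation, 11 with an estimated correlation, 55 with fry, which does not compare a list with other genes, and 21 to 24 with 1 library left out. Among lists that lost a call under the estimated correlation, the estimate was 0.0132 to 0.149 for germline markers, cuticle factors, muscle genes, collagens and ribosomal proteins. It was below the preset 0.01 for hedgehog-related genes (0.00306), channels (0.00361) and astacins (-0.0312), so a higher correlation did not end the calls of these 3 lists. Without members known by name pattern only, every call made with the preset correlation was kept. The papain-family list then had too few members to be tested. With the replicate number as a block, 22 list tests passed, and 10 with the block and an estimated correlation. Against the estimated correlation alone, the block added ribosomal proteins at day 7 against day 3 and collagens at day 11 against day 7. For these 2 lists the estimate went from 0.149 to 0.0174 and from 0.116 to 0.00955 with the block. For muscle genes, cuticle factors and germline markers it was no lower with the block (0.0989, 0.0336 and 0.0341, against 0.0952, 0.0261 and 0.0132). The block ended the calls of the proteasome at day 7 against day 3 and of muscle genes and astacins in L4 against L3. The cause of these losses was not tested. In Wolbachia the block gave 85 higher and 106 lower at day 14 against day 11, and 359 genes over the 4 days.

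The 98 named B. malayi values gave 1851 values under alternatives, of which 1840 kept their call, 11 kept only their direction and 0 reversed. The 15 Wolbachia values gave 293, of which 281 kept their call, 6 kept only their direction and 6 reversed. Reversed, with the worm's library sizes, were Wbm0138 (log2 1.81) and Wbm0495 (2.34) at day 7 against day 3, Wbm0454 (0.34) and Wbm7018 (0.48) at day 11 against day 7, and Wbm0454 (2.00) and wBmNew0014 (2.06) in L4 against L3. Thinning, with fewer counts and fewer genes tested, ended the calls of Wbm0239 at day 7 (log2 0.91 against 0.93, adjusted p = 0.117), Wbm0454 at day 11 (-1.06 against -0.99, 0.165) and Wbm0459 at day 14 (-0.51 against -0.99, 0.546). Depth limits the Wolbachia calls between days 3 and 7. With 200 simulated genes changed, 29.9% of 2-fold changes were called there against 85.1% between days 7 and 11. With fewer genes changed these percentages may differ.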

Other observations

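The tests of explanations, the other groupings of the libraries, the genes highest or lowest at day 7 and the symbol families were chosen only after the results were seen, while the worm's library sizes and effective host sizes had been chosen earlier.

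The Wolbachia share of reads rose from day 3 to day 14 by 4.87 on the log2 scale. A few abundant Wolbachia IDs carrying it is argued against by a rise of 4.63 with the 2 most abundant left out, and a few B. malayi IDs lowering the host total by a rise of 5.17 with effective host library sizes. Reads of a few B. malayi transcripts counted on Wolbachia IDs is argued against by the 658 of 658 tested Wolbachia genes that were higher in L4 with the worm's library sizes. A change in depletion that moved ribosomal RNA alone is argued against by the median log2 change of these 658 genes, 3.26, against 3.31 for the share. More bacteria per larva, more RNA per bacterium and an uneven action of the exonuclease that reached beyond ribosomal RNA stay open as candidate explanations, and none of them was tested.

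Libraries of the same replicate number deviated together from their day means in B. malayi, with a median correlation across genes of 0.330. For other numbers the median was -0.230, a negative value that follows from the centring on day means. Over the 7249 matched IDs alone the same-number median was 0.228 (0.0821 to 0.391), against 0.484 over the 1715 unmatched. That argues against the unmatched IDs as the whole carrier of the shared deviation. An effect of the library that acts alike on both organisms could be the source, since the Wolbachia median, 0.0570, lay within the 0.0410 to 0.101 of 20 draws of B. malayi IDs thinned to the same counts. A difference between the animals or pools behind the numbers was not tested and stays open.

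Fewer Wolbachia genes were called between days 3 and 7, 7 in all, than in the later steps. With the libraries of days 7 and 11 thinned to the totals of days 3 and 7, their comparison still gave a median of 43 calls (32 to 53), which argues against lower counts as the whole cause of that gap. With those of days 11 and 14 thinned in the same way, the median was 12.5 (6 to 21), so lower counts may account for that gap.

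For comparisons of 3 libraries with 3, 10 splits cannot give a share under 0.05. The real split and the highest other gave 4962 and 0, 4715 and 0, and 2569 and 0 B. malayi genes in the 3 steps (edgeR), and 7 and 1, 165 and 1, and 139 and 1 Wolbachia genes; in each, 1 split of the 10, the real one, reached the real value. Over 100 draws of the day labels, the real one included, 1 draw reached the 4941 B. malayi genes of L4 against L3 (highest other 1323) and 1 the 6922 over the 4 days (2632). The same held for Wolbachia, with 1 draw at 177 genes (highest other 67) and 1 at 308 (184). Placing single libraries in days at random thus did not give such counts in the other draws. Whole days were not regrouped, so for L4 against L3 the draws cannot tell a difference between stages from one between days. The replicate numbers pair the B. malayi libraries, and of 50 draws that kept 1 library of each number per day, 0 reached the B. malayi gene counts of L4 against L3 (edgeR; highest 1616) or of the 4 days (2675). For the number of list calls chance is not excluded. There 2 of 100 draws gave at least the real 23 (highest other 24), but of the 50 draws that kept 1 library of each number per day, 6 did (highest 26).

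Some genes outside those named by rule had their highest or lowest mean level at day 7, with libraries that did not overlap those of day 3 or day 11. Bma-ptr-13 stood at 0.140 CPM at day 3, 73.7 at day 7 and 9.13 at day 11, and Bma-daf-9, whose C. elegans counterpart makes a steroid hormone, at 0.346, 60.2 and 7.02. The astacin gene Bma-toh-1 stood at 5.54, 135 and 21.9 CPM on those days, and the peroxidase gene Bma-skpo-3 at 0.293, 32.0 and 13.9. Among genes lowest at day 7, Bma-ecr-1, an ecdysone receptor homologue, stood at 401, 28.4 and 56.8 CPM and the nuclear receptor gene Bma-rxr-1 at 50.8, 2.65 and 5.09.

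Families of genes that share a symbol stem were tested with camera, with the p-values adjusted over all families in each of the 4 comparisons. The calls numbered 8 at day 7 against day 3, 5 at day 11 against day 7, 3 at day 14 against day 11 and 10 in L4 against L3. All of them were lost with an estimated correlation, where the lowest adjusted p values were 0.447, 0.146, 0.116 and 0.356, so the families below are a selection that no call supports under that setting. Rab GTPases, 17 tested, fell in 15 and rose in 1 at day 11 against day 7 (adjusted p = 0.000372, and 0.146 with an estimated correlation), and rose in 12 and fell in 1 at day 14 against day 11 (0.000272, and 0.116 with an estimated correlation). Nuclear pore genes went the other way, with 13 of 21 up at day 11 (0.000717, and 0.423 with an estimated correlation) and 7 down at day 14 (0.0276, and 0.492 with an estimated correlation). All 7 minichromosome maintenance genes rose between days 3 and 7 (0.00227, and 0.447 with an estimated correlation), 4 of 5 cadherins fell in that step (0.0185, and 0.447 with an estimated correlation), and 11 of 24 DnaJ genes rose between days 11 and 14 (0.0292, and 0.459 with an estimated correlation).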
